A study of Homo sapiens with 79 samples.

How the data were processed

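Reduced-representation bisulfite sequencing was used on MCF-7 cells with wild type TET2 and on 2 TET2 knockout lines, 2 libraries each. Per the labels' protocols, genomic DNA was cut with MspI, which cuts at CCGG and enriches for CpG-rich sequence, size-selected, converted with bisulfite, and made into libraries with a random-primed kit. The labels' protocols also state that conversion was followed with spiked lambda DNA; that control was not used here. The series holds 79 samples, of which the 6 bisulfite libraries were analysed; the 73 others, which measure chromatin or transcripts, were not analysed here.

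Per the submitters' processing notes, the tools named for the series include bcl2fastq 2.17.1.14, Trimmomatic 0.33, Trim Galore 0.4.3, Bowtie 1.1.2, TopHat2 2.1.0 and Bismark 0.16.3, and the builds hg19 and GRCh37; the notes as used here do not tie each tool to an assay. The deposited files give, per cytosine of a CpG, the percent methylated and the count of methylated and of unmethylated calls, one table per library with no pooling of replicates. The deposited counts are raw whole numbers, and the deposited percent matched the methylated share of the counts within 0.0001 points in each row. Positions were on hg19 and are printed 1-based. Whether duplicate reads were removed is not given in the sources used here, so calls are not all independent molecules and counting intervals are lower bounds on the error. Calls of neighbouring CpGs can also come from the same read, with the same effect. Where reads are counted below, as in the minimums per tile, the unit is the call.

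Both strands of a CpG were merged, which gave 16786416 CpGs over the 6 libraries. Autosomes and chromosome X were tested. CpGs were summed into 500 bp tiles with at least 2 CpGs and at least 20 calls in each library, which left 34629 tiles. Methylated and unmethylated counts were tested with the edgeR 4.0.16 quasi-likelihood test, with 1 coefficient per library for coverage and group coefficients for methylation, on R 4.3.3. A tile was called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of group means of at least 10 percentage points. The contrasts were the average of the knockout lines against WT, each line against WT, and KO2 against KO1, all from 1 model of 6 libraries. Alternatives were edgeR's likelihood ratio test, limma 3.58.1 on logit methylation with 0.5 reads added, other coverage minimums, tile sizes and difference limits, thinning to equal calls, a replicate block, and leaving out each library in turn, for which a lone library is assumed to vary like the other groups.

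The tests, samples, thresholds and alternatives of the comparisons of tiles, of the global mean and of the region classes were fixed before the data were examined. Chosen after seeing the data were the 100 kb bins, the classes by the mean of 6 libraries, the removal of the deepest 0.1% of tiles, the limits of the CpG number classes, the split of the WT libraries between the lines, the comparison and tests of read depth between lines, the tests of bisulfite conversion and of added DNA, and the window on chromosome 20. The tests of matched CpGs, of lost copies and of the surrounding 100 kb were added after the calls, before their own outcome was seen. The 100 kb bins used CpGs with fewer than 10 observed CpGs within 250 bp and at least 100 calls per bin in each library. Read depth between lines was compared per 1 Mb after a lowess fit (fraction 0.3) on the number of CpGs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6 were used for levels, exact tests and intervals.

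Regions were named by a rule fixed beforehand: the 5 gained and 5 lost tiles with the largest difference in the average contrast among tiles called in both lines in the same direction. The rule gave 5 gained tiles and no lost tile. The other regions named were chosen after their values were seen. Promoters, gene lists, motif-bearing tiles and CpG islands were part of the design but were not run, because a genome and annotation of build hg19 were not used here; classes by the number of observed CpGs took their place, and regions are given by coordinates without gene names. The edgeR tests were tested on simulated libraries with the real coverage and spread and 200 changed units: for the 34629 tiles, 38% of changes of 50 points and 0.5% of changes of 20 points were recovered, with 1.30% and 0% false calls, and for KO2 against KO1 in the 27992 bins, 63% of changes of 15 points and 98% of changes of 25 points, with 3.08% and 1.01% false calls. On the same simulated tiles the likelihood ratio test made 29 false calls of 53 (54.7%) at 20 points and 61 of 203 (30.1%) at 50 points. The quasi-likelihood test made 0 of 1 and 1 of 77. These shares depend on the 200 planted changes and on 1 spread value per group for all tiles. They need not hold for the real calls.

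Methylation of replicates differed by more than counting noise, with a chi-square per degree of freedom of 3.94 in WT, 2.83 in KO1 and 2.62 in KO2, and each library was counted on its own. Duplicate reads and calls that share a read also raise this value. It therefore does not show whether the libraries of a group came from separate samples. Across tiles, which are not independent replicates, replicates correlated at r = 0.895 in WT, 0.928 in KO1 and 0.934 in KO2.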

Results

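DNA methylation was measured in MCF-7, an oestrogen receptor-positive human breast cancer cell line, with intact TET2 and in 2 lines of MCF-7 in which TET2 was knocked out. TET2 encodes a dioxygenase that oxidises 5-methylcytosine, the first step of active demethylation, and the study's title and design text ask what its loss does to enhancers and gene expression in breast cancer cells. The 3 groups, wild type (WT), knockout line KO1 and knockout line KO2, held 2 reduced-representation bisulfite libraries each, 6 in all. The libraries are named here by group and replicate. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The deposited files of a group carry the same sample number and differ by a letter, which leaves open that they are repeated preparations or runs of 1 sample.

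Depth was low at single cytosines. Total methylation calls were 18563211 and 23804552 in the WT libraries, 25923779 and 24038646 in KO1, and 25815461 and 20363863 in KO2, with a median of 2 calls per cytosine in each library. Over the 34629 tiles of 500 bp that were tested, the median number of calls per tile ran from 35 in WT replicate 1 to 49 in WT replicate 2. At a level of 50% such a tile carries a 95% binomial counting error of 16.6 and 14.0 points, respectively. This covers counting error only and takes calls as independent, so it is a lower bound. The targeted gene was not checked by these files, which hold methylation of CpGs and not transcripts or alleles.

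The first comparison asked whether methylation as a whole differed between cells with and without TET2. Both knockout lines lay above WT at well-covered CpGs. These were the 15972 CpGs, of 16786416 seen, with at least 10 calls in every library. Over them, mean methylation was 51.8% ± 0.947 (SD, n = 2) in WT, 53.5% ± 0.0312 (SD, n = 2) in KO1 and 55.7% ± 0.155 (SD, n = 2) in KO2. The average of the knockout lines exceeded WT by 2.78 points, and each of the 4 knockout libraries lay above both WT libraries. CpGs methylated over 80% made up 36.6% ± 0.992 (SD, n = 2) of these sites in WT, 39.0% ± 0.0443 (SD, n = 2) in KO1 and 41.0% ± 0.385 (SD, n = 2) in KO2, while CpGs under 20% made up 32.5%, 31.3% and 28.7%. The 2-sided exact permutation test of the mean over the 6 libraries gave p = 0.133, the smallest value that 15 arrangements allow. When CpGs were weighted by their calls, KO1 exceeded WT by 0.00772 points and KO2 by 4.08 points (exact permutation p = 0.4 for both lines against WT). Over all calls, with no minimum per CpG, the WT libraries stood at 58.7% and 50.3% and the knockout libraries at 56.1 to 59.1%.

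The second comparison asked which regions gained or lost methylation when TET2 was knocked out. In the average of the knockout lines against WT, 16 tiles gained methylation and 1 lost it. These counts moved with the setting, to 30 and 11 at a minimum of 10 reads, 5 and 0 at 50 reads and 41 and 14 with the replicate block. The likelihood ratio test gave 339 and 50. On simulated tiles it made 29 false calls of 53 and 61 of 203, shares that need not hold for the real calls. The 16 gained tiles of the main setting had a median level of 16.0% in WT and 81.7% in the knockout lines, with differences from 18.7 to 90.4 points. In all 16 tiles, each of the 4 knockout libraries lay above both WT libraries; the tiles were called on these libraries, so the 6.67% that chance gives for tiles taken without regard to their values is no test of this count. They lay on chromosomes 1, 2, 3, 4, 8, 10, 14, 17 and 20, with 5 on chromosome 20. The tile that lost methylation, at chr19:31842001-31842500 (hg19), stood at 29.5% ± 1.74 (SD, n = 2) in WT, 2.98% ± 1.17 (SD, n = 2) in KO1 and 2.91% ± 1.17 (SD, n = 2) in KO2 (edgeR adjusted p = 0.0479). Unadjusted p was under 0.05 for 2787 of the 34629 tiles, 1997 of them higher in the knockout lines. Of the 16 gained tiles, 13 were still called without WT replicate 1 and 12 without WT replicate 2, 11 and 7 without KO1 replicates 1 and 2, and 11 and 9 without KO2 replicates 1 and 2, and all 16 kept their direction. The totals moved more, to 23 gained and 2 lost without WT replicate 1, 75 and 98 without WT replicate 2, and 8 and 9 gained without the second replicate of KO1 and of KO2; none passed with limma or after thinning to equal reads. In simulated libraries of the same depth and spread, the edgeR test recovered 38% of changes of 50 points but 0.5% of changes of 20 points, so most changes of the smaller size would be missed at this depth.

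**Figure D1:**
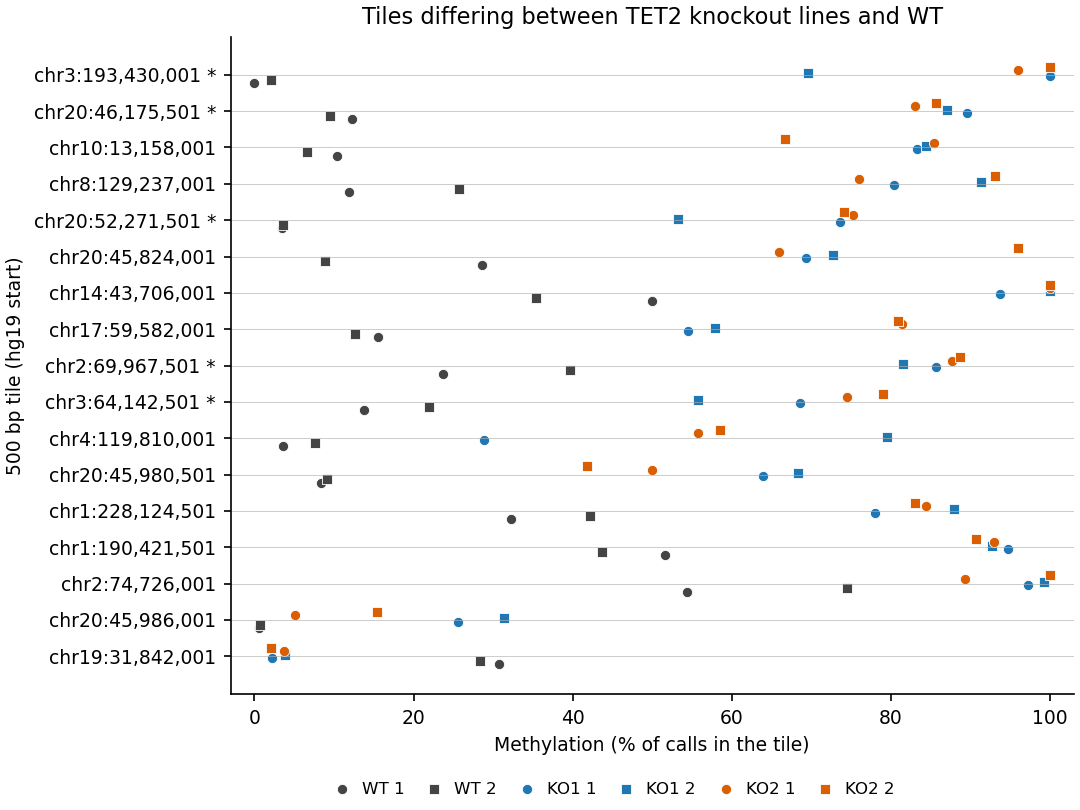
Methylation per library (x axis, percent of calls) at the 17 tiles of 500 bp called in the average of the TET2 knockout lines against WT (y axis, hg19 start). Circles are replicate 1, squares replicate 2, and asterisks mark the 5 tiles called in both lines separately. The 16 gained tiles have all 4 knockout libraries to the right of both WT libraries; the tile on chromosome 19 has them to the left.

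Of the gained tiles, 5 were called in each knockout line by itself. At chr3:193430001-193430500, methylation was 1.02% ± 1.44 (SD, n = 2) in WT, 84.8% ± 21.5 (SD, n = 2) in KO1 and 98.0% ± 2.83 (SD, n = 2) in KO2, on 23 to 80 calls per library. WT replicate 1 had 0 of 40 calls methylated there, which would allow a level of up to 7.50% if calls were independent. The calls cover 15 CpGs and can share reads, so the true limit may be higher. At chr20:46175501-46176000 the levels were 10.9% ± 1.97, 88.3% ± 1.76 and 84.4% ± 1.92 (SD, n = 2 each), and at chr20:52271501-52272000 they were 3.51% ± 0.0870, 63.4% ± 14.4 and 74.7% ± 0.792 (SD, n = 2 each). The tile at chr2:69967501-69968000 went from 31.7% ± 11.3 to 83.6% ± 2.96 and 88.2% ± 0.694 (SD, n = 2 each), and that at chr3:64142501-64143000, with 271 to 497 calls per library, from 17.9% ± 5.77 to 62.2% ± 9.04 and 76.7% ± 3.20 (SD, n = 2 each). Their edgeR adjusted p in the average contrast ran from 9.8e-05 for chr3:64142501 to 0.00209 for chr20:46175501.

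Taken line by line, 9 tiles were gained and 2 lost in KO1, and 10 were gained and none lost in KO2 (edgeR quasi-likelihood test; unadjusted p under 0.05 in 2345 tiles, 1561 higher, for KO1 and in 2530 tiles, 1930 higher, for KO2; limma called none). The losses in KO1 lay at chr2:230045501-230046000, 34.2% ± 8.79 in WT against 12.1% ± 4.28 in KO1, and at chr21:9826001-9826500, 25.8% ± 2.62 against 4.28% ± 1.17 (SD, n = 2 each). Both were chosen after their values were seen. Calls at the first numbered 470 and 661 in the WT libraries and 2259 and 1545 in KO1, and at the second 167 and 141 against 957 and 294. No loss in KO1 was called without the deepest 0.1% of tiles. No tile was called in opposite directions in the 2 lines. The 5 shared gains stand beside 0.0026 for independent lists of that length, a value that leaves out the shared WT libraries. In 10 simulated sets of unchanged groups no tile was gained in either line, so the simulated overlap of 0 gives no measure of chance for lists of 9 and 10. Over all tiles the differences of KO1 and of KO2 from WT correlated at r = 0.570 against 0.585 in simulations with no effect, since both share the WT libraries, and had the same sign in 68.6% of tiles against 69.2%. Their covariance was 88.9 against 64.4 simulated, a difference of 24.5 squared points. With each line set against a different single WT library, a split chosen after the data were seen, the covariance was 22.4 and 21.1, against -3.07 to 2.58 in simulations with no effect. Without single libraries the KO1 gains ran from 1 (without KO1 replicate 1) and 4 (without KO1 replicate 2) to 21 (without WT replicate 1) and 49 (without WT replicate 2), and the KO2 gains from 0, 4 and 6 (without KO2 replicate 2, KO2 replicate 1 and KO1 replicate 1) to 18 and 50 (without WT replicates 1 and 2). Without WT replicate 2 the losses were 67 in KO1 and 57 in KO2, and the shared gains ran from 0 (without KO1 replicate 1 or KO2 replicate 2) and 1 (without KO1 replicate 2) to 8 and 16 (without WT replicates 1 and 2).

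By class of region, the mean difference was largest where methylation was intermediate and smallest among the CpG number classes at CpG-dense tiles. The average of the knockout lines exceeded WT by 3.18 points in the 24270 tiles with 2 to 9 CpGs, by 3.12 points in the 9058 with 10 to 19 CpGs and by 0.908 points in the 1301 with 20 or more. The CpG-dense tiles stood at 45.0% ± 1.90 in WT, 45.5% ± 0.228 in KO1 and 46.3% ± 0.306 in KO2 (SD, n = 2 each), a difference below the spread of the WT libraries, and it was -0.433 points without WT replicate 2. Tiles between 20 and 80% in WT stood at 50.6% ± 1.46 in WT, 53.5% ± 0.0943 in KO1 and 58.6% ± 0.202 in KO2 (SD, n = 2 each). Tiles over 80% in WT differed by -0.270 points and tiles under 20% by 4.08 points. Sorting tiles by WT itself pulls the low class up and the high class down, and with tiles sorted by the mean of the 6 libraries the same differences were 0.241 points below 20%, 6.01 points between and 2.09 points above 80%. Of the 16 gained tiles, 11 were under 20% in WT, and by the mean of the 6 libraries 1 was under 20% and 14 were between 20 and 80%; both levels enter the call, so these counts are descriptive. Gained tiles had fewer than 10 CpGs in 5 of 16 cases against 70.1% of tested tiles, and 20 or more CpGs in 3 of 16 against 3.76% (Fisher's exact test, 2-sided, p adjusted over 6 classes 0.00304 and 0.0308). They also carried more calls, with a median of 98.5 per library against 42.

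The 2 knockout lines share the labelled genotype, and their difference gives the scale of change between lines. At tile level a single tile separated them, chr1:121484001-121484500, with 8582 to 16806 calls per library against a median of 42 over tested tiles. It stood at 39.9% ± 0.472 in WT, 40.6% ± 0.858 in KO1 and 51.7% ± 0.196 in KO2 (SD, n = 2 each). The edgeR adjusted p for KO2 against KO1 was 0.00161. CpG-sparse sites of the surrounding 100 kb were also higher, at 66.5 and 67.0% in the KO2 libraries against 56.3 and 56.6% in KO1. No tile was called without the deepest 0.1% of tiles or with a minimum difference of 25 points. Unadjusted p was under 0.05 for 1860 tiles, 1159 of them higher in KO2; limma called none, 16 and 15 tiles were called without WT replicates 1 and 2, and none without any 1 knockout library.

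Because single tiles were shallow, a further comparison, chosen after the data were seen, used CpGs in CpG-sparse sequence (fewer than 10 observed CpGs within 250 bp) summed over bins of 100 kb. KO2 was higher than KO1 in 1635 of 27992 bins and lower in 132 (edgeR quasi-likelihood test on the 4 knockout libraries, adjusted p under 0.05 and at least 10 points). The higher bins had a median difference of 16.3 points and formed 776 runs of neighbouring bins, the longest of 2600 kb. They were most frequent in partially methylated bins: 23.2% of the 5512 bins between 30 and 70% in the knockout lines were higher in KO2, against 1.63% of bins below and 1.55% of bins above. The class and the call come from the same libraries, and a large difference itself moves a bin towards the middle class. These shares are therefore descriptive. Bins of that middle class averaged 47.3% and 47.7% in the KO1 libraries and 55.5% and 54.2% in the KO2 libraries. In 76.8% of the higher bins both KO2 libraries lay above both WT libraries, against 30.6% of all bins, and in 47.6% both KO1 libraries lay below both of them, against 11.7%. Choosing bins with KO2 above KO1 favours both arrangements. With all sites in place of CpG-sparse CpGs, 465 bins were higher and 65 lower, and with a minimum difference of 25 points 194 and 42. Leaving out 1 knockout library gave 1216 to 1423 higher bins (and 238 lower bins without KO2 replicate 1), limma gave 634, and a model of all 6 libraries, with the wider spread of the WT pair, gave 86.

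Ranked by the difference summed over their bins, and not by length, the largest of these regions lay on chromosomes 4 and X. At chr4:30200001-32600000 methylation was 33.9% ± 0.823 in KO1 and 58.7% ± 0.223 in KO2 (SD, n = 2 each), with 64.3% and 56.5% in the WT libraries. At chr4:188500001-189800000 it was 23.3% ± 1.77 in KO1 and 64.4% ± 0.0470 in KO2, and at chrX:97000001-99600000 48.2% ± 0.113 and 67.4% ± 0.269 (SD, n = 2 each). In the opposite direction, chr4:132700001-135100000 stood at 60.3% ± 1.04 in KO1 and 18.0% ± 0.314 in KO2 (SD, n = 2 each), with 55.8% and 48.6% in the WT libraries. Chromosome 4 held 174 of the higher and 62 of the lower bins, and chromosome X 121 and 3. These were 9.39% and 3.34% of the bins of chromosome 4 and 8.25% and 0.205% of those of X. Of all bins, 5.84% were higher and 0.472% lower, and on chromosome 15 8.60% were higher and none lower. Read depth also differed between the lines on chromosome 4: from 118000001 to 134000000 the log2 ratio of calls in KO2 to KO1 was -0.36, and 36 of the lower bins lay there. From 135000001 to 144000000 it was 0.57, and 37 of the higher bins lay there. Other segments did not follow this: from 106000001 to 117000000 the ratio was 0.63, with 7 higher and 5 lower bins. On chromosome 6, from 1 to 32000000, it was -0.39 with 22 higher bins and 1 lower.

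**Figure D2:**
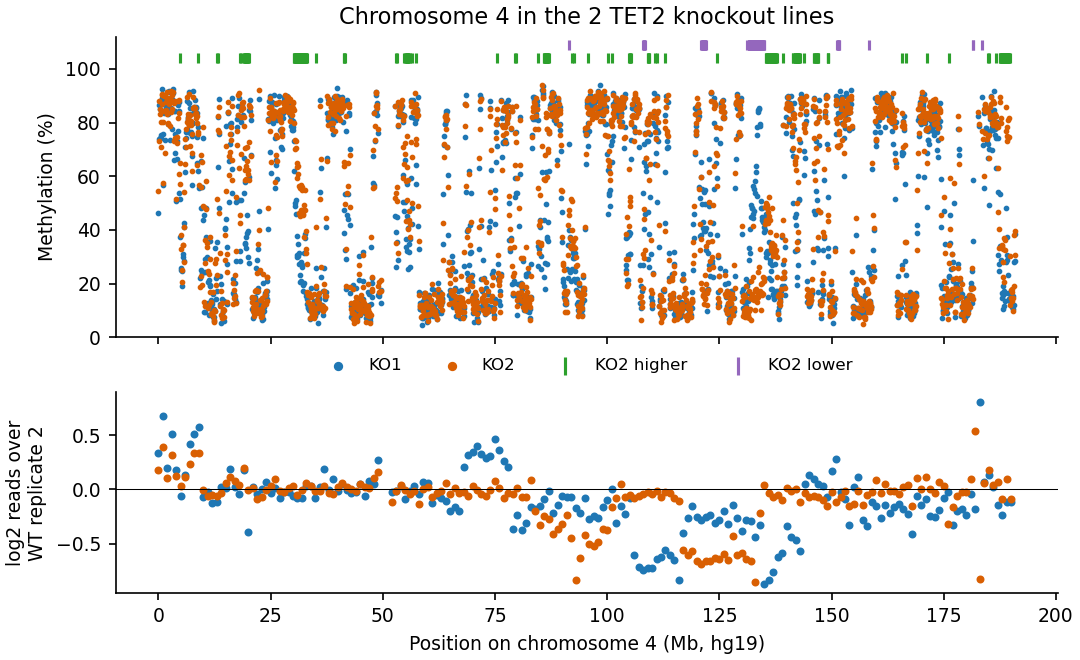
Chromosome 4 in the TET2 knockout lines (x axis, hg19 position in Mb). The upper panel gives the mean methylation of CpG-sparse CpGs per 100 kb bin (percent, mean of 2 libraries) with ticks for the 174 bins higher and 62 lower in KO2; the lower panel gives calls per 1 Mb relative to WT replicate 2 (log2). Of the run of lower bins from 132700001 to 135100000, 3 and 10 bins lie in the 1 Mb windows from 132000001 and 133000001, where KO2 has fewer calls than KO1, and 10 and 1 in the next windows, where it has more.

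In the same 100 kb bins the place of the knockout lines relative to WT depended on the methylation class and on the WT library. In bins over 70%, 49.5% of all, the 4 knockout libraries stood at 82.8 to 83.7% and the WT libraries at 82.7% and 78.5%, a difference of 2.75 points that was 0.643 without WT replicate 2 (exact permutation p = 0.133, the smallest possible). In bins under 30% the 4 knockout libraries, at 14.8 to 16.3%, lay between the WT libraries; from 30 to 70% KO1 lay between them and KO2 at or above the higher one. Mean methylation of the 27962 bins was 60.3% in WT replicate 1 and 51.9% in WT replicate 2, against 55.7% and 55.5% in KO1 and 57.9% and 57.4% in KO2. The gap between the WT libraries was 14.1 points in bins under 30%, 10.2 points in bins from 30 to 70% and 4.22 points in bins over 70%. With all 6 libraries edgeR called 2 bins higher and none lower in the knockout lines (unadjusted p under 0.05 in 2604 bins, 2063 higher; limma called none). Without WT replicate 1, 1845 bins were higher and 32 lower; without WT replicate 2, 470 were higher and 5100 lower; and without any 1 knockout library none were called. The mitochondrial genome read as 62.9% methylated in WT replicate 1 (Wilson 95% interval 61.9 to 63.9, 9303 calls) and as 3.66% in WT replicate 2, against 1.70 and 2.31% in KO1 and at most 2.01% in KO2.

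**Figure D3:**
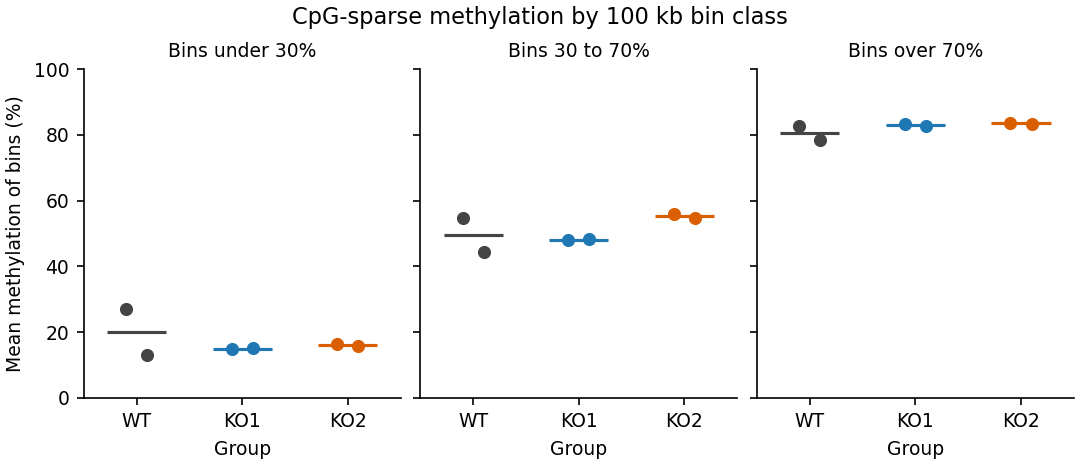
Mean methylation of 100 kb bins of CpG-sparse CpGs (y axis, percent) per library (points) and group mean (line), for bins under 30%, from 30 to 70% and over 70% by the mean of the 6 libraries. KO2 lies above KO1 mainly in the middle class, 55.3% against 48.2%, and the 2 WT libraries lie 14.1, 10.2 and 4.22 points apart.

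**Figure D4:**
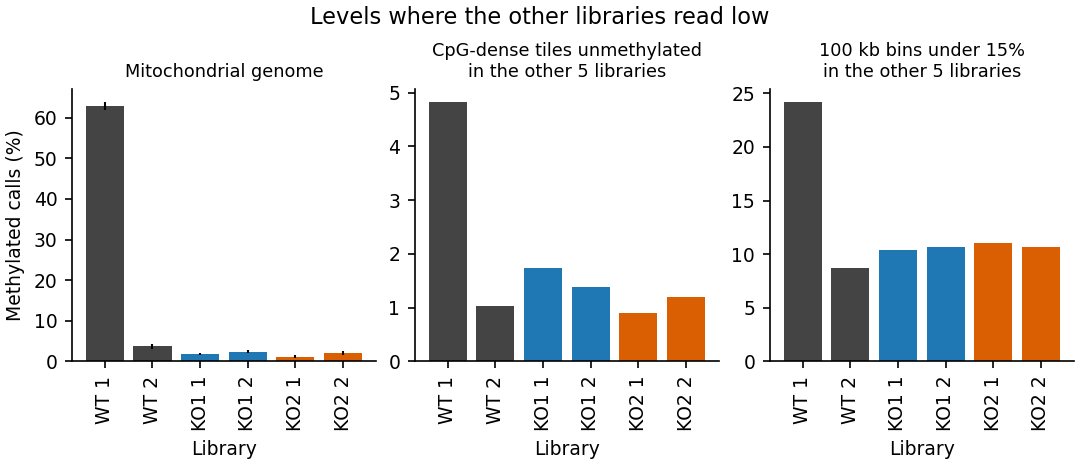
Percent of methylated calls per library (y axis) on the mitochondrial genome (bars with Wilson 95% intervals), in CpG-dense tiles unmethylated in the other 5 libraries, and in 100 kb bins under 15% in the other 5 libraries (single values, no error bar). WT replicate 1 is the highest in each panel, at 62.9%, 4.83% and 24.2% on panels with different scales.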

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

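The tests of the conversion of WT replicate 1, of added DNA and of conversion and copy number between the lines were chosen only after the result was seen; those of matched CpGs, of lost copies and of the surrounding 100 kb were written beforehand.

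The mitochondrial genome, outside the comparisons between groups, read as 62.9% methylated in WT replicate 1, far above the other 5 libraries, which read at most 3.66%. The same library was higher than WT replicate 2 by 14.1 points in the least methylated 100 kb bins. Incomplete bisulfite conversion of that library is consistent with the mitochondrial value, but 1 rate of it in all DNA is argued against, since CpG-dense tiles unmethylated in the other 5 libraries read only 4.83% there, against 0.891 to 1.74%. DNA of another cell type cannot be told apart from it at the 100 kb scale: added DNA would need a methylation of 68.8% if KO2 is taken as reference, 81.8% with KO1 and 108% with WT replicate 2, and only the last is impossible. No biological explanation was tested, since the labels give both WT libraries the same description.

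KO2 and KO1 differed in the test of the difference between the 2 lines, with 1635 bins of 100 kb higher and 132 lower in KO2. A difference in conversion is argued against for the higher bins, because mitochondrial methylation was -0.426 points apart (KO2 minus KO1) where 29.3 points would be needed. The mitochondrial value alone need not follow nuclear DNA, as WT replicate 1 shows. In nuclear tiles with fewer than 10 CpGs, unmethylated in the other 5 libraries, KO1 read 3.54 and 3.44% and KO2 3.39 and 3.44%. Copy number as the whole cause of the higher bins is argued against. Of bins with a depth ratio within 0.2 (log2), 6.01% were higher in KO2. The share was, however, 2.71% where its depth was lower by over 0.35 and 10.3% where it was higher. For the lower bins copy number stays open as a cause. Their share was 4.42% where depth was lower, 0.760% where it was higher and 0.307% within 0.2. Yet 71 of the 132 lower bins lay within 0.2, 13 of them on chromosome 4, and showed no such depth difference. For the higher bins, different CpGs read in different libraries are argued against by CpGs read in all 4 knockout libraries, where the median difference of the called bins was 16.1 points. As a hypothesis, the lines may differ in the methylation of partially methylated domains; whether this came from their derivation, their passage or their TET2 alleles was not tested.

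For the tiles gained in the knockout lines, loss of unmethylated copies is argued against by read depth: the log2 ratio of knockout to WT calls at the gained tiles lay a median of 2.23 above the value such a loss needs, and above it in all 16 (lowest 0.89). That test looks only for a fall in depth, so it does not address added methylated copies, which were not tested. The ratio itself had a median of 0.00798 and ran from -1.95 at chr4:119810001 to 1.76 at chr20:45824001. The surrounding 100 kb rose by a median of 4.35 points where the tiles rose by a median of 54.4. Its CpG-sparse sites already stood at 66.4 to 89.1% in the WT libraries and had little room to rise. This comparison therefore cannot exclude a change of the wider region. A gain that follows loss of TET2 and one that arose when the knockout lines were derived from MCF-7 both remain possible, since each line differs from WT in both respects and no test here separates them; in the 100 kb bins the 2 lines, of the same labelled genotype, also differed from each other.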

How the results depend on the processing

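Promoters, gene lists, motif-bearing tiles, their alternatives and another definition of CpG islands were not run. The global mean difference of 2.78 points covers well-covered CpGs only, 15972 of the 16786416 seen. At such CpGs it kept its direction under each setting tried, from 2.04 (weighted by reads) to 2.87 (without the deepest 0.1% of CpGs). It ran from 2.11 to 3.45 with 1 library left out. The mean over 100 kb bins, given below, did not keep its direction. The direction of more tiles gained than lost held in the average contrast with each setting that made calls except without WT replicate 2 (75 gained, 98 lost). The cause of the changes below was not tested, except where fewer reads or libraries entered by construction. Single tiles of 35 to 49 calls limit what could be called.

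Tile counts are given in the order average gained and lost, KO1 gained and lost, KO2 gained and lost, KO2 against KO1, and gained in both lines, for which the main values were 16, 1, 9, 2, 10, 0, 1 and 5. At least 10 reads gave 30, 11, 17, 4, 16, 2, 1 and 6, and at least 50 reads 5, 0, 2, 0, 4, 0, 1 and 0. Tiles of 1000 bp gave 6, 0, 2, 0, 3, 0, 0 and 0, and single CpGs 7, 1, 3, 0, 11, 1, 5 and 2. The likelihood ratio test gave 339, 50, 129, 28, 212, 27, 65 and 40 and called all 16 main tiles. On simulated tiles with 200 planted changes, 29 of its 53 and 61 of its 203 calls were false. limma and thinning to equal reads gave 0 for each of the 8. No minimum difference gave 2 lost in the average contrast and 3 for KO2 against KO1. A minimum of 25 points, and leaving out the deepest 0.1% of tiles, each gave 0 lost in KO1 and 0 for KO2 against KO1. Leaving out 1 library gave 8 to 75 gained and 0 to 98 lost on average, 1 to 49 and 0 to 67 in KO1, 0 to 50 and 0 to 57 in KO2, 0 to 16 between the lines and 0 to 16 in both lines.

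With the replicate number as a replicate block the tile counts were 41, 14, 26, 7, 26, 9, 3 and 10, and the 100 kb counts of KO2 against KO1 were 1732 and 152. The numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.0866, 0.0896 and -0.0392 between the groups over bins.

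For 100 kb bins of KO2 against KO1 (1635 higher, 132 lower), no minimum difference gave 209 lower, a minimum of 25 points 194 and 42, limma 634 and 81, all sites 465 and 65, and the 6-library model 86 and 23; leaving out 1 library gave 1216 to 1423 higher and 107 to 238 lower. For the knockout lines against WT (2 higher, 0 lower), the replicate block and limma gave 0 higher, and leaving out 1 library 0 to 1845 higher and 0 to 5100 lower. The mean bin difference of 0.498 points became -0.10 with all sites, -0.0723 with 1 read per site, and ran from -3.70 (without WT replicate 2) to 4.70 (without WT replicate 1).

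Class differences with 1 library left out ran from 2.36 to 3.99 points (2 to 9 CpGs), 2.54 to 3.69 (10 to 19), -0.433 to 2.25 (20 or more), 3.58 to 4.57 (WT under 20%), 4.46 to 6.52 (20 to 80%) and -0.964 to 0.423 (over 80%). At least 50 reads gave 0.0918 for 20 or more CpGs (0.908 in the main setting), 4.19 for 20 to 80% and 1.03 for over 80%, and classes by the mean of 6 libraries 0.241 for under 20% and 2.09 for over 80%.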

Other observations

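Of the 16 gained tiles, 4 lay within 352 kb of chromosome 20, from 45824001 to 46176000. At chr20:45824001-45824500 methylation was 18.7% ± 13.9 in WT, 71.0% ± 2.39 in KO1 and 81.0% ± 21.3 in KO2, at chr20:45980501-45981000 8.74% ± 0.581, 66.1% ± 3.17 and 45.9% ± 5.77, and at chr20:45986001-45986500, with 24 CpGs, 0.669% ± 0.0792, 28.5% ± 4.09 and 10.3% ± 7.24 (SD, n = 2 each). The fourth is chr20:46175501-46176000, given above. The span held 131 tested tiles, 0.378% of all, and of the 127 not called 70.1% were higher in the knockout lines, against 59.7% of all tested tiles; the span was picked for its called tiles, and this difference was not tested. In 12 of 100000 random draws of 16 tested tiles, 4 fell within 400 kb of each other; the window was chosen after the tiles were seen, so this share understates chance. For chromosome 20 as a whole, with 6.96% of tested tiles, Fisher's exact test gave p = 0.00371 and, adjusted over 23 chromosomes, 0.0853.

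The knockout lines also differed in read depth over long segments, relative to WT replicate 2 and after correction for the number of CpGs. On chromosome 4, whose long arm carries TET2, KO1 stood at -0.67 and -0.68 (log2, replicates 1 and 2) from 106000001 to 117000000 where KO2 stood at -0.04 and -0.06. From 118000001 to 134000000 the order was the opposite, with KO1 at -0.28 and -0.27 and KO2 at -0.63 and -0.64. KO2 was lower than KO1 from 1 to 32000000 of chromosome 6, by a ratio of -0.39, and higher from 48000001 to 63000000 of chromosome 20, by 0.43. Bins lower in methylation in KO2 made up 4.42% of bins where its depth was lower by over 0.35. They made up 0.760% where its depth was higher by over 0.35 and 0.307% of bins within 0.2. In the first class, 42 of the 44 lay on chromosome 4. These segments were chosen after the data were seen.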
